A study of Mus musculus with 6 samples.

How the data were processed

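RNA from 3 wild-type and 3 β1 integrin knockout mouse hearts at embryonic day 12.5 was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, which read each gene with probes spread along its transcript and give 1 value per transcript cluster. Total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The deposited values are on a log2 scale, as their range shows, and were made by the authors with RMA (robust multi-array average, which corrects background, sets all arrays to a common distribution and summarises the probes of a cluster), per the submitters' processing notes. The version of RMA, the probe annotation, the genome build and any filter are not given in the sources used here. The scanner files were not used here, so no signal over background could be had for single probes, and RMA compresses differences of dim clusters. The design text calls the samples biological replicates. It does not say whether a sample was 1 heart or a pool, so p-values measure the spread between these samples.

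The value table held 28767 transcript clusters and 6 columns, each of which matched the labels of 1 sample. A platform annotation table gave 1 gene symbol for 21776 clusters, several for 1618 and none for 5373. Of those with 1 symbol, 21686 matched a mouse gene table of assembly GRCm38.p6 by Entrez identifier, which was used to update old symbols and to find which genes are neighbours, and not for coordinates. Clusters with several symbols or none were tested but not named. The clusters with 1 symbol stand for 19933 genes. For the 993 genes with several clusters, the cluster with the highest mean over the 6 arrays stands for the gene. 696 clusters held the same values as another cluster.

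Knockout was compared with wild type by limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes on the deposited log2 values, 3 hearts against 3, two-sided, with no covariate. P-values were adjusted by Benjamini-Hochberg over all clusters, with a threshold of 0.05. No filter and no pseudocount was used. Differences are knockout minus wild type on the log2 scale, with the moderated standard error of limma. For Itgb1 an exact two-sided permutation test was run on the 6 values.

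Gene lists were written before the data were examined, from textbook knowledge of the embryonic heart and of integrins, as were the comparison, the rule for named genes and the alternatives. Of 736 list entries 690 were measured. 31 lists were tested with camera, which asks whether the genes of a list lie higher or lower than all other named genes, with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The same lists were tested with the correlation estimated from the data and with fry, which asks whether the genes of a list move one way on balance. A further list of X- and Y-linked sex markers served as a check of the samples and was not tested as a list. Some genes stand in several lists, such as Acta1, Postn, Hey1 and Irx3, so the lists are not independent.

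The rule for named genes took Itgb1, then the 14 genes with the largest rise and the 14 with the largest fall among those past the threshold with no overlap between groups. As 0 genes qualified in either direction, the rule's fallback took the 14 genes of each direction with the lowest p, given as values that did not pass. It further took up to 4 members of each list by lowest p, and every integrin subunit. Genes named outside this rule are the glycolytic enzyme genes, Lyz2, AI506816 and further genes of the closing section, which were chosen after their values were seen.

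The fits were tested on simulated data with the means and spread of the 19933 genes of this comparison. Of genes given a 1.5-fold change 52.2% were called, of those with a 2-fold change 95.5% and of those with a 3-fold change 100%. These were 35, 64 and 66 true calls, beside 19 false calls. The changed genes were drawn only from those at or above the median level, and both groups were given the same spread. The shares therefore do not apply to dimmer genes, nor to genes that vary more in the knockout hearts. A list shifted by 0.3 (log2) among independent genes was called with the preset (adjusted p = 2.66e-15) and the estimated correlation (adjusted p = 0.0237), and 1 other list was called with the preset one. The simulated genes varied independently of each other, which real genes of 1 pathway or cell type do not.

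The alternatives were a filter on dim clusters, 1 cluster per gene, quantile normalization again, cyclic loess, centring on array medians, a trended robust variance, array weights, a replicate block, a fold minimum of 1.5 and leaving out each heart in turn. The number of arrays limits the precision of every value.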

Results

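The series measured gene expression in mouse hearts at E12.5, a mid-gestation stage at which the chambers are growing and trabeculating and the cushions that give rise to the valves are being remodelled. Hearts labelled knockout for β1 integrin were compared with wild-type hearts, 3 of each, on 1 Affymetrix Mouse Gene 1.0 ST array per sample. β1 integrin, encoded by Itgb1, is the shared β chain of most receptors that bind collagen, laminin and fibronectin. The stated aim was to look for early transcript differences at a stage at which the mutant heart still appeared to work. The labels do not say in which cells the gene was deleted, nor whether a sample was 1 heart or a pool. Below, heart stands for 1 sample. Each array gave 1 deposited log2 signal for each of 28767 transcript clusters, and the median signal of the 6 arrays lay between 6.65 and 6.71. With 3 arrays per group, the number of arrays limits the precision, and the median standard error of a knockout minus wild-type difference was 0.11 on the log2 scale.

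The targeted gene was measured first. Itgb1 signal was 11.78 ± 0.02 (SD, n = 3) in wild-type and 11.53 ± 0.12 (SD, n = 3) in knockout hearts. The difference of -0.25 ± 0.09 (SE) left 84.0% of the wild-type signal. The knockout hearts, at 11.53, 11.42 and 11.65, all lay below the wild-type hearts at 11.76, 11.80 and 11.78. The two-sided exact permutation p was 0.1, the smallest that 3 hearts against 3 can give, and limma's adjusted p over all transcript clusters was 0.797. The array's probes for Itgb1 may lie outside the deleted part of the gene, in which case they do not check the labels. Neither the probe positions nor the cells with the deletion are given, so the source of the remaining signal was not tested.

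No single transcript cluster passed limma's test of knockout against wild type. The smallest Benjamini-Hochberg adjusted p over the 28767 clusters was 0.601. At an unadjusted p under 0.05 there were 1705 clusters, of which 880 were higher and 825 lower in the knockout. The other ways to split the 6 hearts into 3 and 3 gave 726 to 2807 such clusters. The knockout values lay wholly above or wholly below the wild-type values for 3629 clusters, or 12.6%, against the 10% that chance gives. Without knockout replicate 1, 1 cluster passed, that of the uncharacterised gene AI506816 (adjusted p = 0.00112), which was 6.10, 6.01 and 5.98 in wild-type and 5.16, 8.76 and 8.93 in knockout replicates 1 to 3. All values of single genes below are therefore measured differences that did not pass the test over all genes.

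Among the 14 higher genes with the lowest p, Cybb, which encodes a subunit of the phagocyte NADPH oxidase, was higher by 0.65 ± 0.11 (log2, SE) in the knockout, and Mpeg1, a pore-forming protein of macrophages, by 0.73 ± 0.12. The C-type lectin receptor gene Clec4n was higher by 0.72 ± 0.14, the complement receptor gene C3ar1 by 0.49 ± 0.10 and the leukocyte activation antigen gene Cd69 by 0.63 ± 0.12. Runx1, a transcription factor of definitive blood formation, had the lowest p of these 14 (limma, adjusted p = 0.601). Its signal was 5.75 ± 0.12 (SD, n = 3) in wild-type and 6.63 ± 0.20 (SD, n = 3) in knockout hearts, a 1.85-fold difference. Sox17, an endothelial transcription factor, was higher by 0.49 ± 0.09, and Sln, which encodes the sarcoplasmic reticulum calcium pump inhibitor sarcolipin, by 0.53 ± 0.11. The other higher genes were the insulin-like growth factor binding protein gene Igfbp3 (0.70), the mechanosensitive channel gene Piezo2 (0.66), the fetal liver glycoprotein gene Ahsg (0.48), the transcription factor gene Msc (0.47), Tceal6 (0.46) and Higd1b (0.39). All 14 were higher in each knockout heart than in any wild-type heart.

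The 14 lower genes with the lowest p were mostly dim. 12 of them, against 11 of the 14 higher genes, lay under the median level of all clusters. The lowest p belonged to Samt2b, at -0.93 ± 0.11 (log2, SE; adjusted p = 0.601), followed by AF366264 at -0.90 ± 0.14. The brighter members were Gpr182, an endothelial G protein-coupled receptor gene, at -0.45 ± 0.08, and the monocarboxylate transporter family gene Slc16a12 at -0.44 ± 0.09. The remaining differences were -0.59 for Stfa3, -0.58 for the olfactory receptor gene Olfr1392, -0.54 for Cd209g and -0.50 for Lce1f. Fbxw22 (-0.50), Magea5 (-0.49), Krt20 (-0.48), Pqlc3 (-0.44), Prame (-0.41) and Spaar (-0.40) completed this set.

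**Figure D1:**
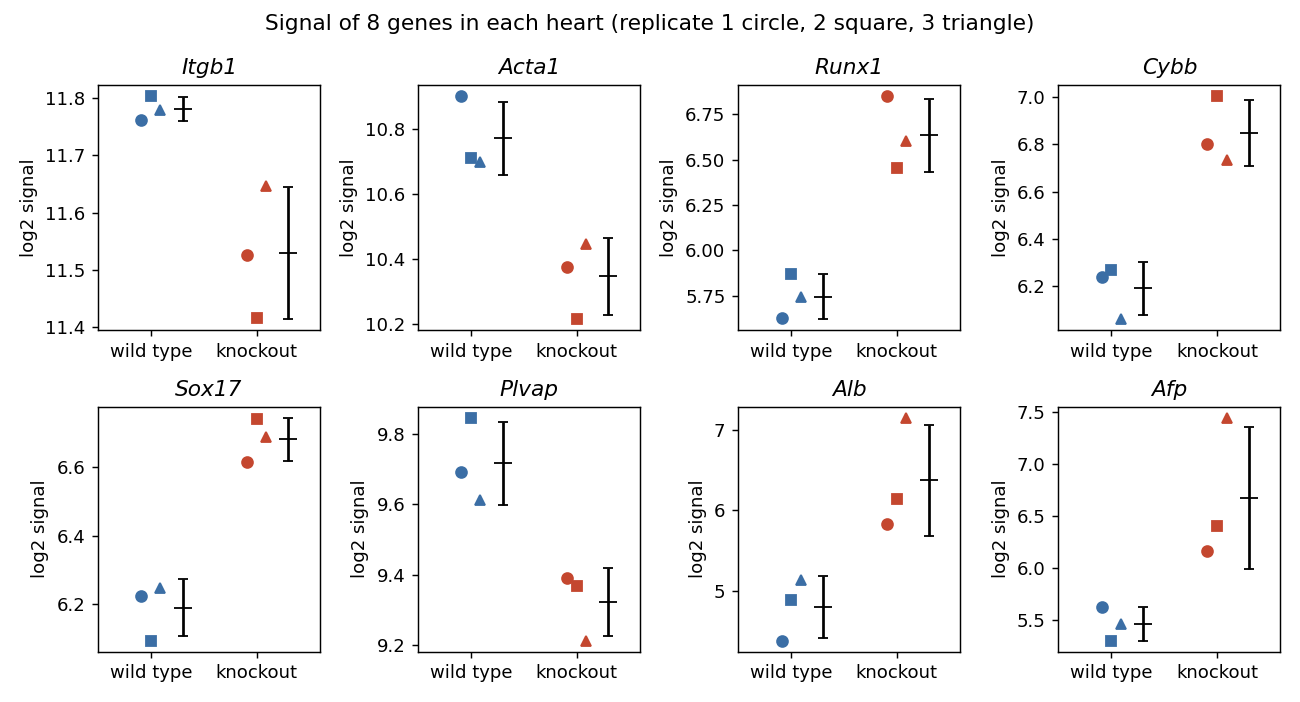
Deposited log2 signal (vertical axes, each with its own range that does not start at 0) of 8 named genes in the 3 wild-type (blue) and 3 knockout (red) hearts, with replicate 1 as a circle, 2 as a square and 3 as a triangle. Horizontal ticks are group means and bars are ± SD (n = 3); Itgb1, Acta1 and Plvap were lower and Runx1, Cybb, Sox17, Alb and Afp higher in every knockout heart than in every wild-type heart.

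Groups of related genes were tested next, as 31 lists of pathway, tissue and cell type genes. With limma's camera test and its preset correlation between genes, 13 lists passed an adjusted p of 0.05, of which 10 were higher and 3 lower in the knockout. None passed when the correlation was estimated from the data, where the smallest adjusted p was 0.537, or with the fry test, where it was 0.351. At an unadjusted p under 0.05, 2 lists passed with the estimated correlation and 3 with fry. With the preset correlation, the other ways to split the 6 hearts into 3 and 3 gave 3 to 16 lists. The count of 13 thus does not set the real groups apart, and the preset p-values below carry this limit. The mean of the list's members separated the knockout hearts from the wild-type hearts for 6 of the 31 lists, 5 of which were among the 13. The other was the cytosolic ribosome list. Chance separates 3 hearts from 3 in 10% of cases. For the sarcomere list the lowest wild-type mean was 11.860 and the highest knockout mean 11.858. With arrays weighted by their quality, 7 lists passed with the preset correlation. These 7 were glycolysis and hypoxia, extracellular matrix, DNA replication, oxidative phosphorylation, liver and foregut, macrophage, and Notch, BMP and FGF signalling. Over all genes tested, 0 members of any list passed limma's test. Adjusted over the list alone, 7 members passed, in 4 lists named below, and 0 in each of the other lists.

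The list of genes of glycolysis and of the response to low oxygen had a higher mean in the knockout hearts. Of 24 measured members 23 were higher and 1 was lower, and 12 lay above all wild-type values. The adjusted p was 1.82e-09 with the preset correlation and 0.673 with an estimated correlation. The mean of the list was 10.03 ± 0.02 (log2, SD, n = 3) in wild-type hearts and 10.51 ± 0.52 (SD, n = 3) in knockout hearts. The members with the lowest p were Egln3, an oxygen-sensing prolyl hydroxylase, at 1.32 ± 0.46 (log2, SE; adjusted p = 0.797), and P4ha1, a collagen prolyl hydroxylase subunit, at 0.72 ± 0.26. The glucose transporter gene Slc2a3 was higher by 1.22 ± 0.50 and the mitophagy receptor gene Bnip3 by 0.69 ± 0.29. The glycolytic enzyme genes of the list differed by 0.64 for Hk2, 0.46 for Aldoc, 0.35 for Pfkp, 0.13 for Ldha, 0.10 for Pkm, 0.08 for Pfkl, 0.07 for Pgk1, 0.07 for Hk1, 0.06 for Aldoa, 0.01 for Tpi1 and -0.03 for Pgam1. Knockout replicate 1 held the largest values, and its list mean lay 1.08 above the wild-type mean, against 0.23 and 0.14 in replicates 2 and 3. Without it, the difference of the list was 0.18 in place of 0.48, and that of Egln3 was 0.71, of P4ha1 0.38, of Slc2a3 0.55, of Bnip3 0.31, of Hk2 0.17, of Aldoc 0.20 and of Pfkp 0.16. Aldoa and Tpi1 both stood at -0.01 and Pgam1 at -0.09 without it, Pgk1 and Pkm at 0.02 and Pfkl at -0.01. These enzyme genes thus showed no clear rise without knockout replicate 1. The same heart was high in erythroid markers, whose mean in it lay 1.16 above the wild-type mean.

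Genes of DNA replication were lower in the knockout hearts. All 29 measured members had a lower mean, 6 of them with no overlap, and the adjusted p was 1.41e-06 with the preset and 0.673 with an estimated correlation. The list mean was 9.17 ± 0.02 (log2, SD, n = 3) in wild-type hearts and 8.99 ± 0.19 (SD, n = 3) in knockout hearts. Mcm7, a subunit of the replicative helicase, differed by -0.25 ± 0.10 (SE), the origin recognition complex gene Orc6 by -0.31 ± 0.13, Gins1 by -0.46 ± 0.21 and the licensing factor gene Cdc6 by -0.22 ± 0.11. Knockout replicate 1 was again farthest, and without it the difference of the list was -0.07 in place of -0.18, with Mcm7 at -0.15, Gins1 at -0.21 and Cdc6 at -0.14. Genes of cell cycle progression had 21 of 29 members lower and did not pass (adjusted p = 0.0676), but passed with a trended robust variance (0.0348) and without wild-type replicate 3 (0.0120) or knockout replicate 2 (0.0466). In that list cyclin E1, Ccne1, differed by -0.35 ± 0.12, Foxm1 by -0.20 ± 0.09, Ccnd1 by -0.25 ± 0.13 and E2f2 by -0.21 ± 0.11. Ccne1 stood at -0.23 and Ccnd1 at -0.12 without knockout replicate 1. Cell cycle inhibitors did not pass either (adjusted p = 0.655). Their lowest p belonged to Cdkn1c, which encodes the inhibitor p57 at -0.26 ± 0.08, while Tob1 stood at -0.15, Rbl2 at 0.23 and Gadd45b at 0.38, the last 2 at 0.15 and 0.08 without knockout replicate 1.

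**Figure D2:**
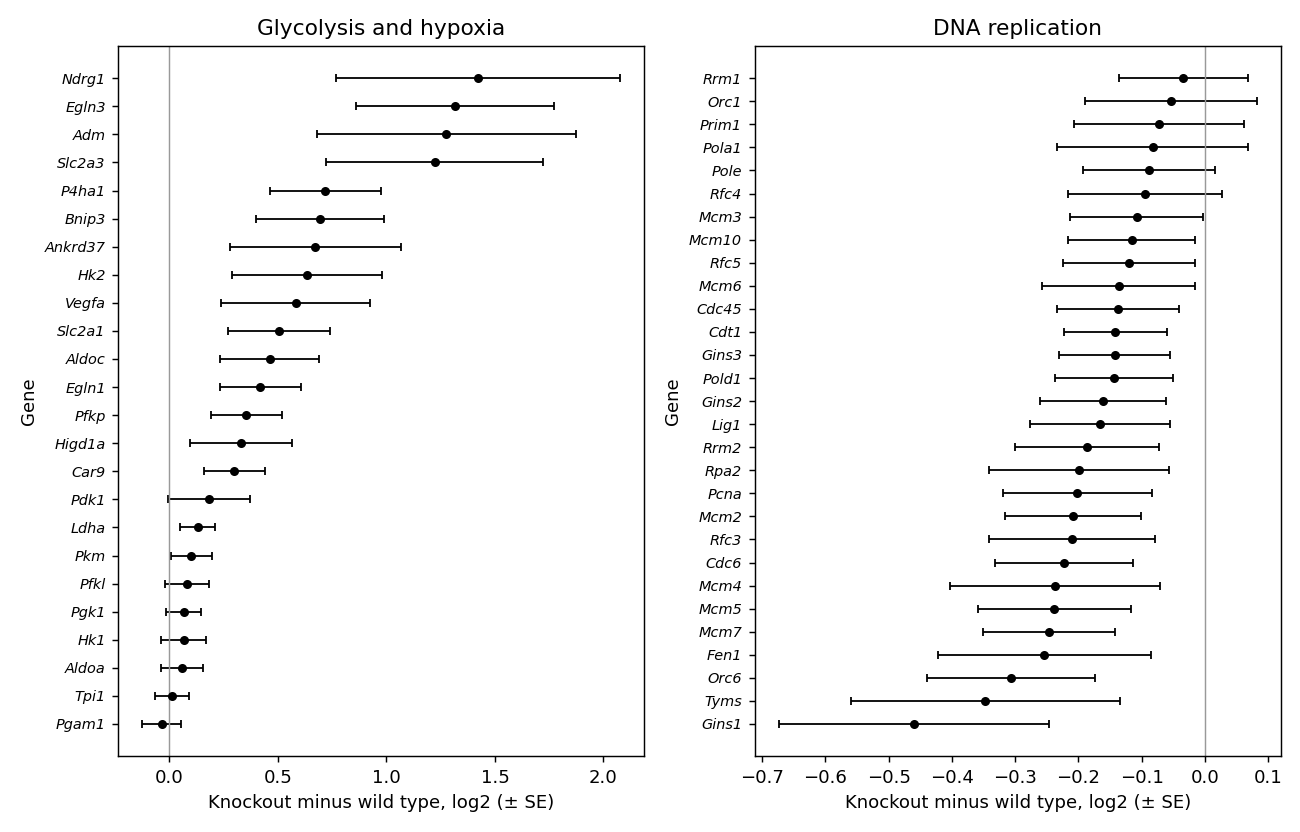
Knockout minus wild-type difference in log2 signal (horizontal axes; points, with bars of ± SE from limma, 3 hearts per group) of each measured member of the glycolysis and hypoxia list (left) and of the DNA replication list (right). Of the 24 members on the left 23 lie above 0, and all 29 on the right lie below 0.

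Genes of oxidative phosphorylation and of the sarcomere were lower in the knockout. For oxidative phosphorylation 28 of 29 members were lower and 1 was higher (adjusted p = 0.000134 with the preset and 0.673 with an estimated correlation). The means of this list overlapped between the groups, at 10.99, 10.97 and 10.83 in wild-type and 10.74, 10.86 and 10.82 in knockout replicates 1 to 3. Sdhb, a subunit of succinate dehydrogenase, differed by -0.42 ± 0.11 (log2, SE), the complex I subunit genes Ndufv1 by -0.22 ± 0.08 and Ndufb9 by -0.24 ± 0.10, and Cox5b by -0.19 ± 0.09. Of 25 sarcomere genes, 20 were lower and 5 higher (adjusted p = 0.00325 with the preset and 0.673 with an estimated correlation). Acta1, skeletal α-actin, which the fetal heart also expresses, was 10.77 ± 0.11 (SD, n = 3) in wild-type and 10.35 ± 0.12 (SD, n = 3) in knockout hearts, a difference of -0.42 ± 0.10 (SE). The myosin light chain gene Myl3 differed by -0.21 ± 0.08, the titin cap gene Tcap by -0.37 ± 0.16, and Myom2, which encodes an M-band protein, by 0.41 ± 0.19. The call of the sarcomere list was lost without wild-type replicate 1 (adjusted p = 0.0883) and without knockout replicate 1 (adjusted p = 0.0855), with differences of -0.07 and -0.05 in place of -0.10.

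Genes of the extracellular matrix were higher in the knockout, with 23 of 24 members higher and 1 lower. The adjusted p was 2.27e-07 with the preset and 0.633 with an estimated correlation. Tnc, which encodes the adhesion-modulating glycoprotein tenascin C, was 7.51 ± 0.73 (SD, n = 3) in wild-type and 8.79 ± 0.70 (SD, n = 3) in knockout hearts, a 2.44-fold difference. Thrombospondin 1, Thbs1, was higher by 1.08 ± 0.41 (log2, SE). The collagen VI chain genes Col6a1 and Col6a2 were higher by 0.36 ± 0.11 and 0.20 ± 0.08, both with no overlap between the groups. The list varied between hearts of one group, with means of 9.55, 9.25 and 9.99 in wild-type and 9.82, 9.75 and 10.39 in knockout replicates 1 to 3. Its difference of 0.39 was 0.22 without wild-type replicate 2, 0.59 without wild-type replicate 3 and 0.19 without knockout replicate 3. The mean of the cushion mesenchyme and valve markers was, in the same hearts, 8.12, 7.84 and 8.68 for wild-type and 8.14, 8.28 and 8.75 for knockout replicates 1 to 3.

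The cushion and valve list was higher in the knockout for 17 of 20 members and lower for 3 (adjusted p = 0.0312 with the preset and 0.795 with an estimated correlation). Its member with the lowest p was the matricellular protein gene Postn, at 0.77 ± 0.35 (log2, SE), followed by Prrx2 at -0.20 ± 0.11, the cartilage collagen gene Col2a1 at -0.28 ± 0.16 and Acan at 0.14 ± 0.11. Prrx2 stood at -0.12 without knockout replicate 1. The call was lost without wild-type replicate 1 (adjusted p = 0.170), wild-type replicate 2 (0.897) or knockout replicate 3 (0.920). Its difference of 0.18 was -0.01 and 0.00 without the last 2, 0.41 without wild-type replicate 3 and 0.30 without knockout replicate 1. In the epicardium and fibroblast list 16 of 21 members were higher and 5 lower (adjusted p = 0.0199 with the preset and 0.633 with an estimated correlation). The epicardial transcription factor gene Wt1 was higher by 0.24 ± 0.10 and the keratin genes Krt19 and Krt8 by 0.58 ± 0.28 and 0.34 ± 0.19, while Lrrn4 stood at -0.28 ± 0.13. Without knockout replicate 1, Krt19 was higher by 0.22 and Krt8 by 0.13. That list lost its call without wild-type replicate 2 (adjusted p = 0.0932) or knockout replicate 3 (0.637), with differences of 0.09 and 0.07 in place of 0.16. Smooth muscle and pericyte genes, 11 higher and 6 lower, did not pass (adjusted p = 0.0866) except without wild-type replicate 1 (0.0192), without knockout replicate 2 (0.00862) or with a replicate block (0.0109), with Notch3 at 0.34 ± 0.13, the calponin gene Cnn1 at -0.23 ± 0.09, Myh11 at 0.27 ± 0.13 and Pdgfrb at 0.37 ± 0.19.

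Among the integrin subunits, 16 of 24 were higher and 8, Itgb1 among them, lower in the knockout (adjusted p = 0.00556 with the preset and 0.633 with an estimated correlation). Itgav, the αv chain that pairs with several β chains, was higher by 0.26 ± 0.11 (log2, SE), Itga9 by 0.22 ± 0.10, Itga10 by 0.16 ± 0.08 and Itgb5 by 0.15 ± 0.08. The largest differences were those of the platelet integrin genes Itga2b (0.97 ± 0.59) and Itgb3 (0.63 ± 0.41) and of the leukocyte gene Itgb2 (0.46 ± 0.31). Without knockout replicate 1, these 3 stood at 0.17, 0.08 and 0.09, and the mean difference of the list was 0.07 in place of 0.15. Itgal (0.29), Itga4 (0.27), Itga1 (0.17), Itga8 (0.14), Itga7 (0.13), Itgb8 (0.10), Itgb4 (0.07), Itgam (0.07) and Itga2 (0.06) were higher by their means. The lower subunits beside Itgb1 were Itga6 (-0.10), Itga5 (-0.06), Itgae (-0.05), Itga3 (-0.04), Itga11 (-0.04), Itgb6 (-0.03) and Itgb7 (-0.03), and each of these 7 except Itga6 turned its sign in at least 1 alternative fit, as did Itga2, Itga8, Itgam, Itgb4 and Itgb8. Itgal stood at 0.12, Itga1 at 0.08, Itga8 at 0.28 and Itgb8 at 0.22 without knockout replicate 1. The call of the list was lost without wild-type replicate 2 (adjusted p = 0.0583). Focal adhesion and integrin adaptor genes, 17 higher and 8 lower, did not pass (adjusted p = 0.0866), but did without wild-type replicate 1 (0.0289). Lims2, an adaptor of integrin-linked kinase, was higher by 0.61 ± 0.17, the kindlin gene Fermt2 by 0.16 ± 0.09 and Nmrk2 by 0.20 ± 0.13, while the muscle integrin-binding gene Itgb1bp2, melusin, stood at -0.45 ± 0.20. Itgb1bp2 stood at -0.23 and Fermt2 at 0.11 without knockout replicate 1. Basement membrane genes, 14 higher and 6 lower, had an adjusted p of 0.0529 and passed in 7 of 15 alternative fits with the preset correlation, with perlecan, Hspg2, at 0.16 ± 0.09, Col4a4 at 0.18 ± 0.11, Lamb1 at 0.16 ± 0.10 and nephronectin, Npnt, at -0.11 ± 0.08. Lamb1 stood at 0.07 without knockout replicate 1.

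The Notch, BMP and FGF signalling list and the actin cytoskeleton list had higher means in the knockout, with overlap between the hearts of the groups. Of 30 genes of Notch, BMP and FGF signalling 22 were higher and 8 lower (adjusted p = 0.000959 with the preset and 0.633 with an estimated correlation). The Notch targets Hey1 and Heyl were higher by 0.30 ± 0.09 and 0.31 ± 0.14 (log2, SE), Smad7, an inhibitor of TGF-β and BMP signalling, by 0.54 ± 0.20 and Hes1 by 0.21 ± 0.12, or 0.12 without knockout replicate 1. The list means were 8.21, 8.06 and 8.35 in wild-type and 8.32, 8.27 and 8.43 in knockout replicates 1 to 3, beside cushion marker means of 8.12, 7.84 and 8.68 and of 8.14, 8.28 and 8.75. This call was lost without wild-type replicate 2, with an adjusted p of 0.0718 and a difference of 0.06 in place of 0.13. The difference was 0.20 without wild-type replicate 3 and 0.09 without knockout replicate 3. Of 25 genes of the actin cytoskeleton and of SRF or YAP targets, 18 were higher and 7 lower (adjusted p = 0.00556 with the preset and 0.633 with an estimated correlation). The immediate early genes Fosb and Egr1 were higher by 0.67 ± 0.19 and 0.48 ± 0.23, Tagln2 by 0.35 ± 0.15 and the non-muscle myosin gene Myh9 by 0.26 ± 0.12. Without knockout replicate 1 the actin list had an adjusted p of 0.0855 and a difference of 0.07 in place of 0.13, with Egr1 at 0.22 and Myh9 at 0.16.

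The lists of leukocyte, liver and foregut, and erythroid markers also passed, with the preset correlation only. In the macrophage and leukocyte list 17 of 20 members were higher and 3 lower (adjusted p = 0.000178 with the preset and 0.537 with an estimated correlation). The lysosomal membrane gene Laptm5 was higher by 0.56 ± 0.17 (log2, SE; 0.36 without knockout replicate 1), the Fc receptor γ chain gene Fcer1g by 0.34 ± 0.13 and Coro1a by 0.33 ± 0.13. The lysozyme genes Lyz1 and Lyz2, which macrophages also express, went the other way, at -0.28 ± 0.12 and -0.40 ± 0.17. Liver and foregut genes were higher for 18 of 21 members and lower for 3 (adjusted p = 1.37e-05 with the preset and 0.537 with an estimated correlation). Alb was 4.80 ± 0.38 (SD, n = 3) in wild-type and 6.37 ± 0.69 (SD, n = 3) in knockout hearts, 2.98-fold higher, and Afp was 5.47 ± 0.16 and 6.67 ± 0.68, 2.30-fold higher. Alb and Afp encode the main proteins that fetal hepatocytes and yolk sac secrete. Both were dim here, under the median level of all clusters, at percentiles 32.1 and 40.6, as was Ahsg at 24.9. Adjusted over the list alone, Ahsg and Alb (limma, adjusted p = 0.0201) and Afp (0.0312) passed, while the transferrin gene Trf stood at 0.26 ± 0.09. In the erythroid list all 17 members were higher by their means (adjusted p = 0.000333 with the preset and 0.673 with an estimated correlation). The list lay 1.16 above the wild-type mean in knockout replicate 1, and stood at -0.11 and -0.03 relative to it in replicates 2 and 3. Its lowest p belonged to Nfe2 at 0.36 ± 0.21, Rhag at 0.75 ± 0.47, Gata1 at 0.33 ± 0.23 and Tspan33 at 0.29 ± 0.20. Without knockout replicate 1 the direction of the list turned and its adjusted p was 0.639, with Nfe2 at 0.10, Rhag at 0.12, Gata1 at 0.06 and Tspan33 at 0.03.

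**Figure D3:**
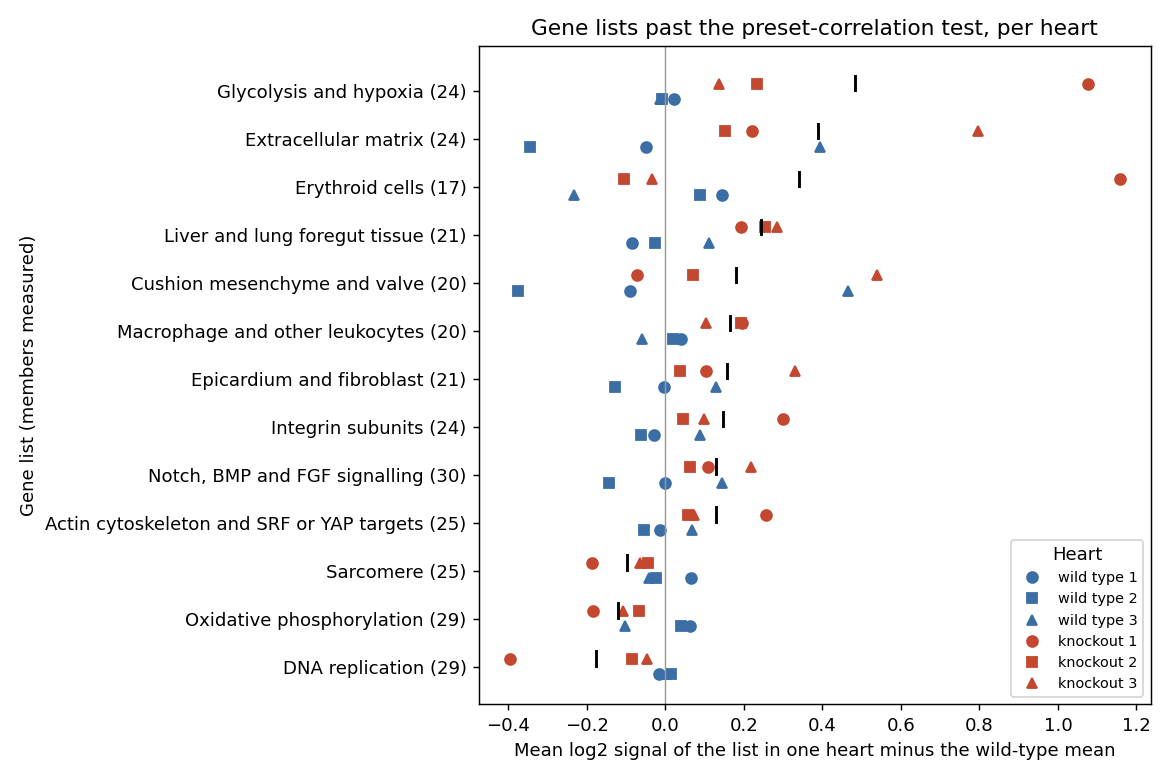
Mean log2 signal of each of the 13 lists that passed the preset-correlation test, in each heart, minus the mean of the 3 wild-type hearts (horizontal axis; rows are lists with their number of measured members). Blue marks are wild-type and red marks knockout hearts, and black ticks are knockout means; knockout replicate 1 (red circles) lies 1.08 above the wild-type mean for glycolysis and hypoxia and 1.16 above it for erythroid cells.

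In the endothelium and endocardium list, which did not pass as a whole (adjusted p = 0.738), 2 genes passed adjusted over the list alone. Sox17 was higher (limma, adjusted p = 0.0121), and Plvap, which encodes the diaphragm protein of endothelial fenestrae, was lower at -0.39 ± 0.10 (log2, SE; adjusted p = 0.0475). Flt4 stood at 0.24 ± 0.11 and Tek at -0.22 ± 0.12, or -0.11 without knockout replicate 1. Cardiac transcription factors had 14 members higher and 14 lower (adjusted p = 0.961), with Hey1 above, Irx3 at -0.30 ± 0.09, Irx4 at -0.28 ± 0.12 and Nkx2-5 at -0.17 ± 0.08. Genes of trabecular and compact myocardium were split 10 and 10 (adjusted p = 0.961), with Cited1 at -0.23 ± 0.09, Sema3a at -0.21 ± 0.09 and Smpx at -0.23 ± 0.12. The cardiac stress list had 11 higher and 8 lower members (adjusted p = 0.852), with the small heat shock protein gene Hspb1 at -0.27 ± 0.11, the galectin gene Lgals3 at 0.51 ± 0.22 (0.26 without knockout replicate 1), and Acta1 and Postn as above. Of the calcium handling and ion channel genes 7 were higher and 16 lower (adjusted p = 0.782). Their median of -0.04 and mean of 0.05 differed in sign, and the test leaned higher. The mean was 0.09 without wild-type replicate 1, and 0.03 without wild-type replicate 2 or 3. Without wild-type replicate 3 the test leaned lower. Sln passed adjusted over that list alone (adjusted p = 0.0290), Cacnb2 stood at -0.22 ± 0.09, Cacna1g at 0.47 ± 0.19 and Kcnj2 at 0.71 ± 0.33, the last at 0.29 without knockout replicate 1.

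The remaining lists did not pass in the fit described here. Fatty acid oxidation had 7 members higher and 13 lower (adjusted p = 0.0644, but 0.0294 with a filter on dim clusters, 0.0210 with a trended robust variance and 0.00131 without wild-type replicate 3), with Cpt2 at -0.24 ± 0.09 (log2, SE), Decr1 at -0.21 ± 0.09, Ech1 at -0.22 ± 0.09 and Slc25a20 at -0.24 ± 0.10. Sterol biosynthesis had 4 higher and 13 lower (adjusted p = 0.0728, but 0.00336 without wild-type replicate 3 and 0.0405 without knockout replicate 3), with Nsdhl at -0.32 ± 0.11. In the unfolded protein and amino acid stress list, 12 higher and 10 lower (adjusted p = 0.655), the chaperone cofactor gene Sdf2l1 stood at -0.31 ± 0.08 and the serine synthesis gene Phgdh at -0.45 ± 0.13, while Trib3 stood at 0.61 ± 0.30, or 0.21 without knockout replicate 1. Neural and neural crest genes had 13 higher and 5 lower members (adjusted p = 0.738). The dopamine β-hydroxylase gene Dbh, at -0.47 ± 0.11, passed adjusted over that list alone (adjusted p = 0.0463), and the endothelin receptor gene Ednrb stood at -0.31 ± 0.11. The interferon list had 8 higher and 10 lower members (adjusted p = 0.738), with a median of -0.02 where the test leaned higher. Genes of p53 targets and apoptosis were 8 higher and 9 lower (adjusted p = 0.961), with Perp at -0.27 ± 0.12 and Apaf1 at 0.18 ± 0.09. The skeletal muscle list was 9 higher and 11 lower (adjusted p = 0.961), with a mean of 0.01 and a median of -0.02. Cytosolic ribosome genes had 4 higher and 18 lower members (adjusted p = 0.766), with list means of 11.63 ± 0.004 (SD, n = 3) in wild-type and 11.61 ± 0.01 (SD, n = 3) in knockout hearts that did not overlap.

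Knockout replicate 1 stood apart from the other arrays. Its signals correlated across clusters with those of the other knockout hearts at r = 0.988 and 0.991, where pairs of wild-type hearts lay between 0.995 and 0.996. In it 433 clusters lay more than 1 log2 unit from the median of the other arrays, against 113 in knockout replicate 3 and 20 to 51 in the other 4. Sex markers differed between samples within each group and were not balanced between the groups. Xist, expressed from the inactive X chromosome of females, was 8.37, 11.26 and 4.86 in wild-type and 8.28, 5.71 and 5.01 in knockout replicates 1 to 3. The Y-linked gene Eif2s3y was 9.35, 5.77 and 9.33 in wild-type and 9.12, 9.37 and 9.41 in knockout replicates 1 to 3. Wild-type replicate 1 and knockout replicate 1 thus had signal from both, which argues against either sample holding tissue of 1 embryo alone. For the other samples the question of 1 heart or a pool stays open. Wild-type replicate 2 was the only sample low in Y-linked signal, and the fit held no term for sex. The integrin, Notch, cushion and epicardium calls were lost without that sample, and the matrix difference shrank. Whether sex had a part in these changes was not tested.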

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

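The alternative that left out knockout replicate 1 and wild-type replicate 2 together was chosen after seeing the data; the others were planned. The count of clusters past the threshold was 0 in all fits except those without knockout replicate 1. With 1 heart left out it ranged from 0 to 1, as did the count of higher clusters, and with those 2 hearts left out both counts were 1. This cluster was AI506816 both times (2.82 and 2.81, adjusted p = 0.00112 and 0.0196). The Itgb1 difference stayed between -0.33 and -0.20. The 13 lists became 7 with array weights, 4 with the 2 hearts left out, 0 with an estimated correlation and 0 with fry, and 9 to 16 with 1 heart left out. The extracellular matrix, macrophage, liver and foregut, and glycolysis and hypoxia lists passed in every fit except with an estimated correlation or fry. The DNA replication and oxidative phosphorylation lists were otherwise lost only with the 2 hearts left out (adjusted p = 0.181 and 0.153). Of the lists that did not pass in the planned main comparison, basement membrane passed in 7 of 15 alternative fits with the preset correlation (adjusted p from 0.00622 to 0.742), cell cycle progression, smooth muscle and fatty acid oxidation in 3 each, sterol biosynthesis in 2 and focal adhesion in 1. The fatty acid oxidation list passed with the filter on dim clusters (0.0294), the trended robust variance (0.0210) and without wild-type replicate 3 (0.00131). The cushion list turned without knockout replicate 3 (adjusted p from 2.93e-07 to 0.920 over the 6 fits with 1 heart left out) and the erythroid list without knockout replicate 1 (3.51e-07 to 0.639). The erythroid turn comes from leaving out the 1 heart whose erythroid signal was high; the cause of the other changes was not tested. With a replicate block 0 clusters and 14 lists passed, and Itgb1 stood at -0.25. Hearts of one number did not deviate together (residual r = -0.04, -0.03 and -0.06), and none correlated best with its own number. No shared deviation by number was thus detected, which does not exclude that hearts of one number were handled together. Among 167 genes followed, 0 passed in any fit and 15 turned sign at least once, in 24 of 2453 values, none larger in size than 0.13. Such turns of genes past the threshold in neither fit were not counted as reversals, a rule set after seeing them, nor were those of 11 lists that never passed while turned. No scaling moved the median difference of all clusters by over 0.1. The filter on dim clusters left too few liver and foregut and neural genes to test. A pseudocount did not apply to log2 values. Signal over background was not used here, so how far background limits the differences of dim clusters is open.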

Other observations

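The tests of the 3 weighed patterns, the correlation of 2 lists among them, and the genes named here outside the lists were chosen after the results were seen; the counts over other splits of the hearts were planned.

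Over all genes measured, members of the lists included, 24 were over 2-fold higher by their means in the knockout hearts and 1, Xist, was over 2-fold lower. None passed limma's test over all genes. Xist and the Y-linked genes Eif2s3y and Uty are among the 25, and wild-type replicate 2, the highest in Xist, was the only heart low in Y-linked signal; without it Eif2s3y differed by -0.04. The metallothionein genes Mt2 and Mt1, which encode metal-binding proteins induced by metals, glucocorticoids and stress, were higher in each knockout heart than in any wild-type heart. Mt2 was 7.42, 7.38 and 7.38 in wild-type and 10.84, 8.67 and 8.23 in knockout replicates 1 to 3. Mt1 differed by 1.00 ± 0.37 (log2, SE); without knockout replicate 1, Mt2 differed by 1.05 in place of 1.85 and Mt1 by 0.52. Gpnmb, a lysosomal glycoprotein gene of macrophages and other cells, was higher by 1.13 ± 0.30 (limma, adjusted p = 0.797), and Plek and Srgn, expressed in platelets and leukocytes, by 1.09 ± 0.37 and 1.14 ± 0.49. The prostaglandin synthase gene Ptgs2 was higher by 1.29 ± 0.54, the neuronal enolase gene Eno2 by 1.31 ± 0.51 and the connective tissue genes Dpt and Meox1 by 1.15 ± 0.43 and 1.08 ± 0.51. With knockout replicate 1 left out, Plek stood at 0.61, Srgn at 0.48, Ptgs2 at 0.56 and Eno2 at 0.62. Dpt and Meox1 stood at 0.69 and 0.68 without wild-type replicate 2, and Meox1 at 1.68 without wild-type replicate 3. In 16 of the 24 genes knockout replicate 1 was the highest knockout heart, and 9 of the 24 stayed over 2-fold higher without it.

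Some genes were far higher in knockout replicate 1 than in any other heart, and those named here were picked for that gap. Ppbp was 9.81 in it and 6.54 to 7.18 in the other 5 hearts, and Pf4 was 8.89 in it and 6.33 to 6.63 in the others. Itga2b was 9.74 in it and 7.09 to 7.50 elsewhere, and Tubb1 9.49 against 7.21 to 7.53. The embryonic globin gene Hbb-bh1 was 10.95 in it and 8.19 to 9.18 elsewhere. In total 97 genes were over 1 log2 unit higher in that heart than in the next heart, against 9 in knockout replicate 3 and 0 or 1 in each of the others.

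The first pattern is the higher glycolysis and hypoxia list. For the list mean, knockout replicate 1 was not the only source. The lower of the means of knockout replicates 2 and 3 still lay 0.115 above the highest wild-type heart, with a wild-type SD of 0.019. The list was already known to separate the groups, so this gap was no independent test. It does not cover every member: without knockout replicate 1, Pgk1 stood at 0.02, Aldoa at -0.01 and Pgam1 at -0.09, while Hk2 stood at 0.17 and Aldoc at 0.20. Blood cells might bring transcripts of the list, yet in knockout replicates 2 and 3 the erythroid list did not exceed the wild-type mean, the higher of the 2 lying -0.035 from it. That value is within the wild-type SD of 0.203, knockout replicate 1 was high in both lists, and the macrophage and leukocyte list in knockout replicates 2 and 3 (6.84 and 6.75) lay above the highest wild-type heart (6.68), so blood cells stay open. A time without oxygen before or during dissection, and a response of the mutant heart itself, were not tested and stay open.

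The second pattern is the higher extracellular matrix list. It may follow the share of cushion and outflow tissue in a sample: with shared members left out, the deviations of the matrix and cushion lists from their group means correlated at r = 0.943 over the 6 hearts (exact permutation p = 0.0556 over 36 reorderings within groups; Spearman's rho = 0.886, p = 0.0833). Without wild-type replicate 3 and knockout replicate 3, the hearts farthest from the median, r was 0.405 over the other 4 hearts. Leaving out the most extreme hearts itself tends to lower r, so this value does not settle on which hearts the relation rests. The share of cushion and outflow tissue cannot be told apart from an effect of genotype. The wild-type hearts alone spanned 0.645 (log2), against a difference of 0.367 between the groups for the members kept. Knockout replicate 1 as the only source is argued against, as 122% of the list's difference was left without it.

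The third pattern concerns Ccdc7a, next to Itgb1 on one side in the order of tested genes, which was lower in the knockout by a difference of -0.35 ± 0.09 (log2, SE; limma, adjusted p = 0.797) at a dim level of about 3. A block of genes that differs with the targeted allele could give this, and would be seen as several differing neighbours where several were tested. Of the 30 tested genes nearest to Itgb1, 1 had an unadjusted p under 0.05, equal to the median of 652 windows of 30 genes elsewhere, whose 95th percentile was 4. That 1 is Ccdc7a itself, which prompted the test, while 0 of the other 29 did so and Nrp1, next to Itgb1 on the other side, differed by -0.01. Ccdc7a was the only tested gene on its side of Itgb1, so the count could not show a block on that side. On the other side no excess of differing neighbours was seen, but so few genes do not exclude a small block. A block stays open, as does an effect on Ccdc7a itself, which was not tested.

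The 6 hearts make 10 splits into 3 and 3, the real one included, too few for a share under 0.05. For clusters past the threshold the real split gave 0 and the highest other split 0, so that all 10 gave as many. For lists the real split gave 13 and the highest other 16, with wild-type replicates 1 and 2 and knockout replicate 2 against the rest, and 3 of the 10 gave as many as the real one.

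The 5 clusters annotated to Acp1 disagreed, 1 being higher in the knockout by 1.31 ± 0.16 (limma, adjusted p = 0.601) and the other 4 lying between -0.13 and -0.09. The higher cluster had an unadjusted p of 5.58e-05 (limma), under the 0.000122 of Runx1. It was not among the named genes because a brighter cluster stands for Acp1. Probe positions were not used, so which of the 5 clusters measure the Acp1 gene itself was not tested.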
